A study of Homo sapiens with 8 samples.

How the data were processed

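Poly(A)-selected RNA was sequenced from 8 libraries of HEK293T cells, 4 with empty vector and 4 with the SETMAR plasmid, each well receiving 2 µg of plasmid. Strand-specific libraries were made and sequenced as paired ends, per the labels' protocols. Poly(A) selection leaves little of RNAs without poly(A) tails, such as most replication-dependent histone mRNAs, so many of their values rest on low counts. Some histone genes stood higher, with empty vector means of 88.5 CPM for HIST1H2BK, 36.9 for HIST1H1C and 23.0 for HIST2H2BE. Reads were aligned to hg19 with STAR and counted per gene with featureCounts from Subread, MultiQC and edgeR being named as well, per the submitters' processing notes. Versions, the annotation, the strand setting of the counting the treatment of reads with several alignments and the filter on low genes are not given in the sources used here, so values of near-identical and overlapping genes depend on unknown settings. The deposited table holds raw counts per gene and log2 CPM values in each library, per the file headers. The authors' deposited table also holds a log2 fold change, a p-value and an FDR for each gene, which were compared with the values computed here and entered no test. A further deposited table holds read numbers and mapping shares per library, and another the RNA integrity numbers, per the file headers.

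The counts as deposited were the starting point. All 13706 listed genes entered, and edgeR's filterByExpr left out 3, so 13703 were tested. TMM factors set the library sizes, and SETMAR was compared with empty vector by edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3, robust fit, group as the only term) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 without a fold limit. CPM in the text are on TMM-adjusted library sizes, and standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 4.77%. Depth ran from 17324126 to 30556039 counts per library, and errors quoted as SD are over 4 libraries and cover the spread between libraries only.

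The text names SETMAR, up to 12 genes in each direction with the largest log2 fold changes among those past the threshold (mean CPM of at least 1, groups not overlapping, clone-based symbols and pseudogenes left out) and up to 4 members of each gene list with the smallest adjusted p. Only 11 genes qualified as higher, SETMAR among them. The 34 gene lists, the tests of genes and lists between the groups and this rule were fixed before the data were examined. The tests of S phase, a general heat shock response, plasmid sequence in GH1 and neighbouring genes in the closing section were chosen later. Outside the rule, HSPA1A and HSPA1B were named for the test of reads shared with HSPA6, whose prediction was written before that test was run. Others, such as HIST1H2BN, H1F0, MALAT1, NEAT1 and the members of pairs of neighbouring genes, were chosen after their values were seen. Lists with 5 or more members tested, 32 in all, were tested with limma's camera (version 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2). The mitochondrially encoded and hepatocyte lists had 0 members in the table. Library measures were compared by two-sided exact permutation tests over 12 measures.

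Alternatives fixed beforehand were RLE and upper-quartile factors, SETMAR left out of the library sizes, DESeq2 (version 1.42.0), the edgeR likelihood ratio test, limma-voom, no filter, a CPM of at least 1 in 4 libraries, each library left out in turn, the replicate number as a block, glmTreat against a fold of 1.2, and for the lists an estimated correlation, fry and a minimum of 10 members. Thinning all libraries to 17324126 counts and offsets from loess fits on GC content, length and level were chosen after seeing the data.

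The steps were tested on simulated data drawn from the means, dispersions and library sizes of these samples, with 200 genes changed. Over 20 simulated sets of 13703 genes for the comparison of SETMAR with empty vector, edgeR's quasi-likelihood test recovered 62.1% of genes changed 1.2-fold, 91.8% at 1.5-fold, 99.2% at 2-fold and 100% at 4-fold. False calls made up 5.86% of its calls on average, from 2.34 to 10.7% over the sets. The likelihood ratio test had 10.1% false calls over 3 of those sets. In a simulated set of 20 lists, camera called the 1 list shifted by 0.15 and 0 of the other 19. Genes were drawn independently there, so correlation between members of a list was not simulated. The shift was also larger than the median of every real list but the histone list.

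Gene types, GC content and transcript sequences came from GENCODE release 29, in which 94.9% of the listed symbols were found. Its coordinates are on another build, so all coordinates given are those of the deposited table (hg19). The SETMAR coding sequence of 2055 bases was compared with the annotated transcripts by blastn 2.17.0. The plasmid sequence was not used here.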

Results

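RNA was measured in HEK293T cells, a human embryonic kidney cell line that is easily transfected. The cells had received either an empty expression plasmid (empty vector, n = 4 libraries) or the same plasmid carrying full-length wild-type SETMAR (n = 4 libraries), and were harvested 48 h after transfection. SETMAR is a human protein in which a SET histone methyltransferase domain is joined to a domain derived from the transposase of an Hsmar1 mariner transposon. The comparison asks which transcripts differ when SETMAR is overexpressed, the purpose stated in the series description. No plasmid carrying another gene was among these samples, so an effect of SETMAR cannot be told apart from one of expressing any gene strongly. The deposited table listed 13706 genes. Total counts per library ran from 17324126 to 30556039, and each SETMAR library was deeper than each empty vector library. Counts averaged 26910200 ± 3635850 with SETMAR and 20366900 ± 2056500 with empty vector (SD, n = 4 per group). The exact permutation test gave a two-sided p = 0.0286 (adjusted p = 0.0571 over 12 library measures), 0.0286 being the smallest p that 4 against 4 can give. Within each group, every pair of libraries differed by more than the counting noise of 1 library sequenced again, which does not show that they came from separate cultures. The labels do not state whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

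The transfected gene separated the groups as labelled. SETMAR (hg19 chromosome 3, 4344988 to 4358949, plus strand, protein-coding) averaged 108 ± 25.9 CPM with empty vector and 48440 ± 3401 CPM with the SETMAR plasmid (SD, n = 4 per group), a log2 fold change of 8.81 (SE 0.21, edgeR quasi-likelihood adjusted p = 7.9e-06) and a 448-fold difference. The counts of SETMAR were 1874, 2092, 3210 and 1833 in empty vector libraries 1 to 4, and 1326215, 1109355, 1477860 and 1181804 in SETMAR libraries 1 to 4. SETMAR took 4.75 ± 0.325% of the counts of a SETMAR library and 0.0110 ± 0.00261% of those of an empty vector library. Gene counts do not separate plasmid-derived from endogenous SETMAR transcripts.

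**Figure D1:**
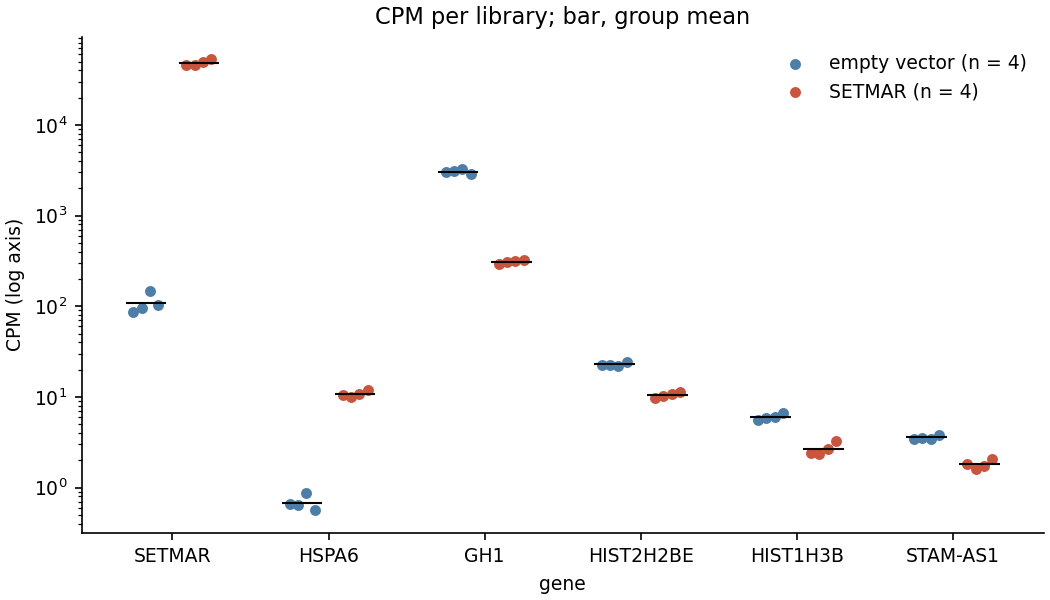
CPM of 6 genes (log axis) in each of the 4 empty vector and 4 SETMAR libraries, with a bar at each group mean. SETMAR rose from 108 to 48440 CPM on average and GH1 fell from 3062 to 309 CPM, and the points of the groups do not overlap in any of the 6 genes.

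Beside SETMAR, a single gene was more than 2-fold higher. HSPA6 (chromosome 1, 161494330 to 161496687, plus strand), a stress-inducible HSP70 chaperone, was detected at 0.679 ± 0.128 CPM with empty vector and 10.8 ± 0.754 CPM with SETMAR, a log2 fold change of 3.97 (SE 0.14, 15.6-fold, adjusted p = 7.4e-14). Its raw counts were 10 to 19 in the empty vector libraries and 245 to 321 in the SETMAR libraries. In the opposite direction, GH1, the pituitary growth hormone gene (chromosome 17, 61994553 to 61996212, minus strand), fell from 3062 ± 172 to 309 ± 12.7 CPM, a log2 fold change of -3.31 (SE 0.04, 9.92-fold lower, adjusted p = 8.5e-22). Both genes have near-identical relatives in the genome, with which reads can be shared, so the assignment to HSPA6 and GH1 is uncertain. Reads counted for GH1 may also come from growth hormone sequence of the plasmid, so the fall need not be one of the GH1 gene.

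In all, 40 of the 13703 genes tested passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 11 higher and 29 lower with SETMAR. Of these, 8 changed by at least 2-fold, 2 higher and 6 lower. The remaining changes were small, with a median absolute log2 fold change of 0.48 once SETMAR, GH1 and HSPA6 were set aside. Every library of one group lay above every library of the other for 1019 genes, 7.44% of those tested, where chance gives 2.86%. The count of 40 depended on single libraries, being 19 without empty vector 1, 26 without empty vector 2, 77 without empty vector 4, 20 without SETMAR 1 and 26 without SETMAR 4. Genes higher were 3, 25, 4, 19, 5 and 5 without empty vector 1, empty vector 3 and SETMAR 1, 2, 3 and 4 in turn, and genes lower were 16, 18, 61 and 16 without empty vector 1, 2 and 4 and SETMAR 1. The count of 40 also depended on the test, being 89 with DESeq2 (31 higher, 58 lower) and 151 with the edgeR likelihood ratio test (68 higher, 83 lower). With the replicate number as a block it was 86 (41 higher, 45 lower), so the excess of lower genes depended on the setting. The authors' deposited table lists 178 genes at an FDR under 0.05 (79 higher, 99 lower), 39 of them among the 40.

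**Figure D2:**
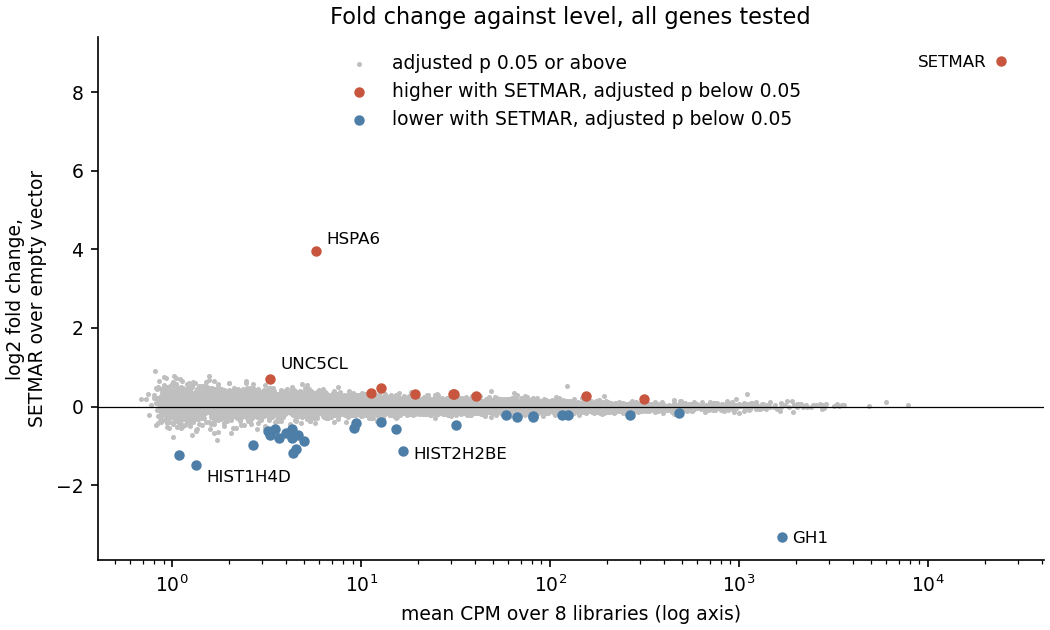
Log2 fold change of SETMAR over empty vector against mean CPM over 8 libraries (log axis) for each of the 13703 genes tested, with the 11 higher and 29 lower genes past the threshold in colour. SETMAR, HSPA6 and GH1 lie far from the remaining genes, with log2 fold changes of 8.81, 3.97 and -3.31.

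The other 9 genes that rose did so by less than 2-fold. UNC5CL had the largest of these changes, from 2.50 ± 0.315 to 4.06 ± 0.477 CPM (log2 fold change 0.70, SE 0.13, adjusted p = 0.0256). HMOX1, the haem oxygenase induced by oxidative stress, rose from 140 ± 6.06 to 169 ± 6.64 CPM (log2 fold change 0.27, SE 0.04, adjusted p = 0.0037). DHRS2, a short-chain dehydrogenase, had a log2 fold change of 0.47 (SE 0.10), and NME2, a nucleoside diphosphate kinase whose reads can be shared with NME1, one of 0.33 (SE 0.07). DOC2A, YPEL3, SLC12A4 (a potassium-chloride cotransporter), ANKZF1 and the ribosomal protein gene RPS29 (uncertain, since ribosomal protein genes have many near-identical copies) had log2 fold changes of 0.36, 0.32, 0.31, 0.26 and 0.20. HSPA6 and HMOX1 stayed past the threshold when any 1 of the 8 libraries was left out. The other 8 did not. With empty vector 1 left out, adjusted p (edgeR quasi-likelihood test) was 0.0586 for UNC5CL, 0.153 for DHRS2, 0.177 for DOC2A, 0.112 for NME2, 0.0879 for YPEL3, 0.112 for SLC12A4, 0.0791 for ANKZF1 and 0.134 for RPS29. With empty vector 2 left out, it was 0.0977 for UNC5CL, 0.156 for DHRS2, 0.0813 for DOC2A, 0.122 for NME2, 0.0977 for SLC12A4 and 0.104 for RPS29. With empty vector 3 left out, it was 0.0522 for NME2. With empty vector 4 left out, it was 0.0563 for DHRS2. With SETMAR 1 left out, it was 0.0542 for UNC5CL, 0.216 for DOC2A, 0.218 for NME2, 0.175 for YPEL3, 0.209 for SLC12A4, 0.0793 for ANKZF1 and 0.209 for RPS29. With SETMAR 2 left out, it was 0.0936 for NME2, 0.0534 for YPEL3 and 0.0866 for RPS29. With SETMAR 3 left out, it was 0.0826 for UNC5CL, 0.129 for DHRS2, 0.111 for DOC2A, 0.0617 for NME2, 0.0530 for SLC12A4 and 0.0890 for RPS29. With SETMAR 4 left out, it was 0.0683 for UNC5CL, 0.131 for DHRS2, 0.108 for DOC2A, 0.0671 for YPEL3, 0.0777 for SLC12A4 and 0.0509 for ANKZF1. With thinned counts it was 0.135 for DHRS2 and 0.0761 for NME2.

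Histone genes were the group with the clearest change. Of the 17 members of the histone list that were tested, all had negative log2 fold changes, with a median of -0.60, and 9 fell at an adjusted p under 0.05 over all genes (14 adjusted over the list alone). The set test gave an adjusted p = 2.9e-27 for this list, and 0.0155 with an estimated correlation. HIST2H2BE (chromosome 1, 149856010 to 149858232, minus strand), an H2B gene, fell from 23.0 ± 1.07 to 10.5 ± 0.659 CPM (log2 fold change -1.13, SE 0.07, adjusted p = 1.7e-09). HIST1H3B, an H3 gene of the chromosome 6 cluster, fell from 6.01 ± 0.457 to 2.67 ± 0.425 CPM (log2 fold change -1.18, SE 0.12), and HIST1H4D, an H4 gene, from 1.96 ± 0.353 to 0.709 ± 0.250 CPM (log2 fold change -1.50, SE 0.22). HIST1H2AC and HIST1H3H fell with log2 fold changes of -1.08 and -0.87, and the linker histone gene HIST1H1C with one of -0.48 (SE 0.06, adjusted p = 0.00012). Among all 27 genes of the table whose symbols start with HIST, 27 had a negative log2 fold change, 11 fell and none rose, and 16 had non-overlapping groups. Their summed CPM was 235 ± 7.44 with empty vector and 166 ± 4.74 with SETMAR (SD, n = 4 per group), the lowest empty vector library at 228 and the highest SETMAR library at 171. Histone genes are near-identical copies whose reads can be split between them, so the value of a single copy is uncertain.

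**Figure D3:**
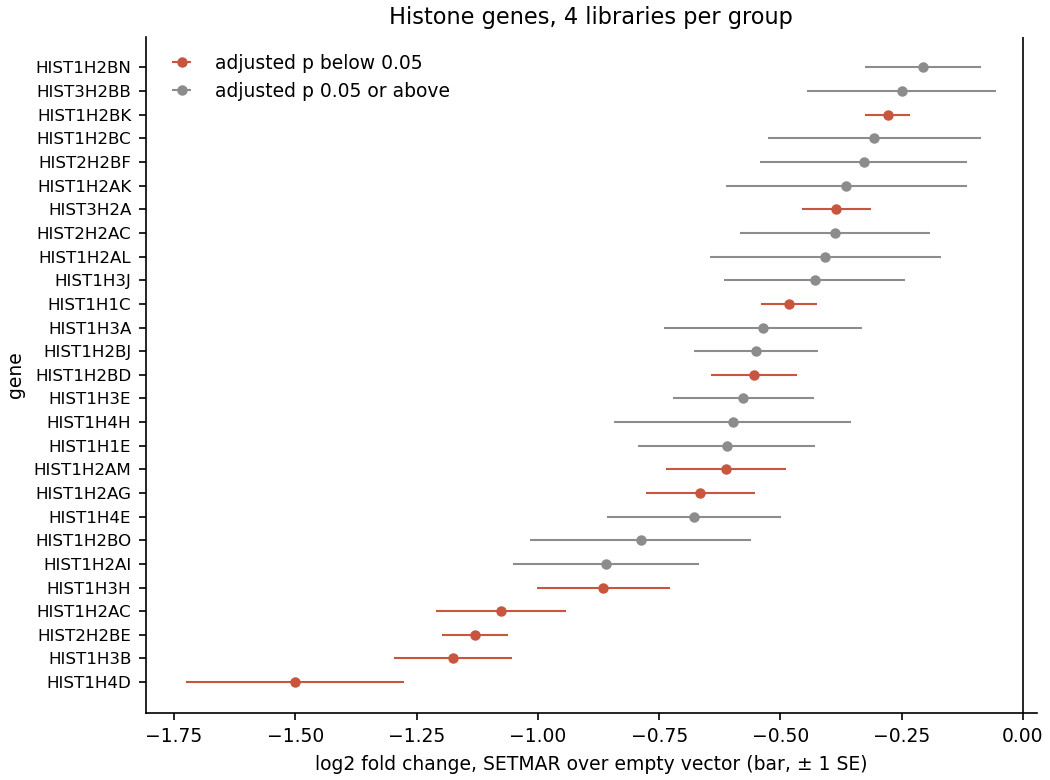
Log2 fold change of SETMAR over empty vector for the 27 HIST genes tested (4 libraries per group), with bars of 1 SE and the 11 genes past the threshold in colour. All 27 points lie below 0, from -0.21 for HIST1H2BN to -1.50 for HIST1H4D.

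Of the 6 other genes with the largest decreases, 3 are annotated as non-coding (C10orf111, STAM-AS1 and C18orf65) and 2 (LOC100272217 and LOC101927765) were not found in the annotation. C10orf111 (chromosome 10, 15137384 to 15139318, minus strand; annotated at a bidirectional promoter) fell from 1.54 ± 0.305 to 0.641 ± 0.232 CPM (log2 fold change -1.22, SE 0.24, adjusted p = 0.0291). STAM-AS1 (chromosome 10, 17683283 to 17685917, minus strand), an antisense RNA beside the gene of an endosomal adaptor, fell from 3.57 ± 0.176 to 1.80 ± 0.192 CPM (log2 fold change -0.99, SE 0.13, adjusted p = 0.00063). LOC100272217, C18orf65 and LOC101927765 fell with log2 fold changes of -0.80, -0.74 and -0.73 (SE 0.13, 0.12 and 0.11). DNAH17, an axonemal dynein heavy chain gene, fell from 4.68 ± 0.786 to 2.67 ± 0.769 CPM (log2 fold change -0.80, SE 0.17, adjusted p = 0.0464). With empty vector 1 left out, adjusted p (edgeR quasi-likelihood test) was 0.138 for C10orf111 and 0.190 for DNAH17. With empty vector 2 left out, it was 0.101 for C10orf111 and 0.0539 for DNAH17. With empty vector 4 left out, it was 0.109 for DNAH17. With SETMAR 1 left out, it was 0.218 for DNAH17. With SETMAR 2 left out, it was 0.0770 for C10orf111 and 0.0899 for DNAH17. With SETMAR 4 left out, it was 0.102 for C10orf111 and 0.0619 for DNAH17. The DNAH17 call was also lost with RLE factors and with thinned counts (edgeR adjusted p = 0.0501 and 0.0740) and with upper-quartile factors, where adjusted p lay at the threshold, and that of C10orf111 with thinned counts (adjusted p = 0.0555). The sources used here do not state whether reads were counted by strand, so reads of STAM-AS1 and overlapping transcripts cannot be told apart.

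The heat shock and stress lists held few changes beside HSPA6. In the heat shock list, 1 of 26 members tested rose over all genes (3 rose and 3 fell adjusted over the list alone), and the median log2 fold change was -0.03 with a camera adjusted p = 0.648. HSPA1B, the abundant inducible HSP70 gene, had a log2 fold change of 0.03 (SE 0.05) and HSPA8, the constitutive one, had -0.15 (SE 0.03, adjusted p = 0.0694). In the integrated stress response list, PPP1R15A, which encodes a regulatory subunit of the eIF2-alpha phosphatase, fell from 125 ± 3.03 to 107 ± 4.17 CPM (log2 fold change -0.22, SE 0.04, adjusted p = 0.0262), and none of the other 31 members passed over all genes. Adjusted over the list alone, 3 of the 32 members rose and 2 fell, PPP1R15A among those that fell. With empty vector 1 left out, adjusted p (edgeR quasi-likelihood test) was 0.118 for PPP1R15A. With empty vector 2 left out, it was 0.0521 for PPP1R15A. With empty vector 3 left out, it was 0.0533 for PPP1R15A. With SETMAR 1 left out, it was 0.204 for PPP1R15A. With SETMAR 2 left out, it was 0.0711 for PPP1R15A. With SETMAR 4 left out, it was 0.0595 for PPP1R15A. In the NRF2 and metal response list 1 of 21 members, HMOX1, rose over all genes (3 adjusted over the list alone), with FTL at 0.14 (SE 0.03) and FTH1 at 0.11 (SE 0.04). No member of the unfolded protein response list (28 tested, median -0.04) or the interferon list (25 tested, median 0.03) passed over all genes, and 0 and 2 rose adjusted over the list alone. At an unadjusted p under 0.05 the edgeR test gave 1595 genes in all.

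Other lists moved together by small amounts. Camera called 13 of the 32 lists with 5 or more members tested, but 12 of these calls were lost with an estimated correlation. Fry kept 4 of the 13 and lost the others. Those kept were the histone (fry adjusted p = 0.00025), p53 target (0.0099), fibroblast and mesenchymal (0.0099) and non-homologous end joining lists (0.0095). The glycolysis and hypoxia response list was higher with a median log2 fold change of 0.09 over 33 members, 32 of them positive (0 rose over all genes and 11 adjusted over the list alone; adjusted p = 3.4e-08, and adjusted p = 0.305 with an estimated correlation). SLC2A3 and SLC2A1, glucose transporter genes, had log2 fold changes of 0.36 (SE 0.09) and 0.20 (SE 0.06). The p53 target list was higher with a median of 0.09 over 31 members (0 rose over all genes, 8 rose and 1 fell adjusted over the list alone; adjusted p = 3.8e-05, and adjusted p = 0.0780 with an estimated correlation), with PHLDA3 at 0.21 (SE 0.05). Cytosolic ribosomal protein genes were higher with a median of 0.04 over 73 members, 66 of them positive (1 rose over all genes, 2 adjusted over the list alone; adjusted p = 3.8e-05, and adjusted p = 0.637 with an estimated correlation). Fibroblast and mesenchymal markers had a median of 0.12 over 16 members (2 rose adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.0780 with an estimated correlation), with COL6A2 at 0.27 (SE 0.06, edgeR adjusted p = 0.0501) and COL3A1 at 0.29 (SE 0.09, adjusted p = 0.216). The TGF-beta and BMP, axon guidance and Notch lists had medians of 0.09, 0.08 and 0.08, with adjusted p = 0.249, 0.286 and 0.478 with an estimated correlation. Their members tested numbered 22, 42 and 21, of which 0 rose over all genes and 0, 2 and 0 rose adjusted over the list alone. Medians moved by over 1.5 times for p53 target genes without empty vector 3 (0.057), for cytosolic ribosomal proteins without empty vector 3, empty vector 4 or SETMAR 2 (0.066, 0.026 and 0.025) and for axon guidance and neuronal adhesion without empty vector 2 (0.052). The Notch call was lost without empty vector 4, SETMAR 1 or SETMAR 2 (adjusted p = 0.287, 0.116 and 0.0610). With offsets for GC content, length and level, the Notch and axon guidance calls were lost, with medians of 0.02 and 0.05 (camera adjusted p = 0.410 and 0.0620).

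Camera called 5 lists lower beside the histone list, each call being lost with an estimated correlation. With fry the non-homologous end joining call was kept (fry adjusted p = 0.0095) and the others of these were lost. In these libraries empty vector 4 stood apart from the other libraries on the first principal component (score -19.0, 27.4% of variance, SETMAR, GH1 and HSPA6 left out). The SR protein and hnRNP list had a median log2 fold change of -0.04 over 44 members (0 fell over all genes, 3 fell and 1 rose adjusted over the list alone; adjusted p = 0.00024, and adjusted p = 0.305 with an estimated correlation), with SRSF3 at -0.14 (SE 0.03) and TRA2B at -0.13 (SE 0.03). DNA replication genes had a median of -0.03 over 50 members, 39 of them negative (0 fell over all genes and 0 adjusted over the list alone; adjusted p = 0.0087, and adjusted p = 0.478 with an estimated correlation), with MCM5 at -0.10 (SE 0.04). Non-homologous end joining genes, a repair route to which SETMAR has been linked, had a median of -0.06 over 25 members (0 fell over all genes and 0 adjusted over the list alone; adjusted p = 0.0230, and adjusted p = 0.194 with an estimated correlation), with XRCC5 at -0.08 (SE 0.04). The mitosis and decatenation lists had medians of -0.03 and -0.03, with adjusted p = 0.637 and 0.683 with an estimated correlation, and 0 and 1 members fell adjusted over the list alone. Both calls were lost without empty vector 4 (adjusted p = 0.700 and 0.889), where those of DNA replication (adjusted p = 0.264) and non-homologous end joining (adjusted p = 0.0732) were also lost. Medians without empty vector 4 were -0.0043 for mitosis and G2/M, 0.0051 for DNA decatenation and chromosome condensation, -0.035 for non-homologous end joining and -0.026 for SR proteins and hnRNP splicing regulators. The DNA decatenation and chromosome condensation list had medians of -0.053 without empty vector 3 and -0.020 without SETMAR 1. The mitosis and decatenation calls were lost as well without SETMAR 1 (adjusted p = 0.140 and 0.123) and without SETMAR 2 (adjusted p = 0.0573 and 0.149), and that of non-homologous end joining without SETMAR 2 (adjusted p = 0.0610). With offsets for GC content, length and level, all 5 camera calls were lost: medians were -0.0016 for DNA replication, -0.015 for SR proteins and hnRNPs, -0.0079 for decatenation, -0.00042 for mitosis and -0.04 for end joining (adjusted p = 0.783, 0.349, 0.599, 0.818 and 0.105). Upper-quartile factors also lost the mitosis and decatenation calls (adjusted p = 0.0524 for each), as did thinned counts (adjusted p = 0.0624 and 0.0671).

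**Figure D4:**
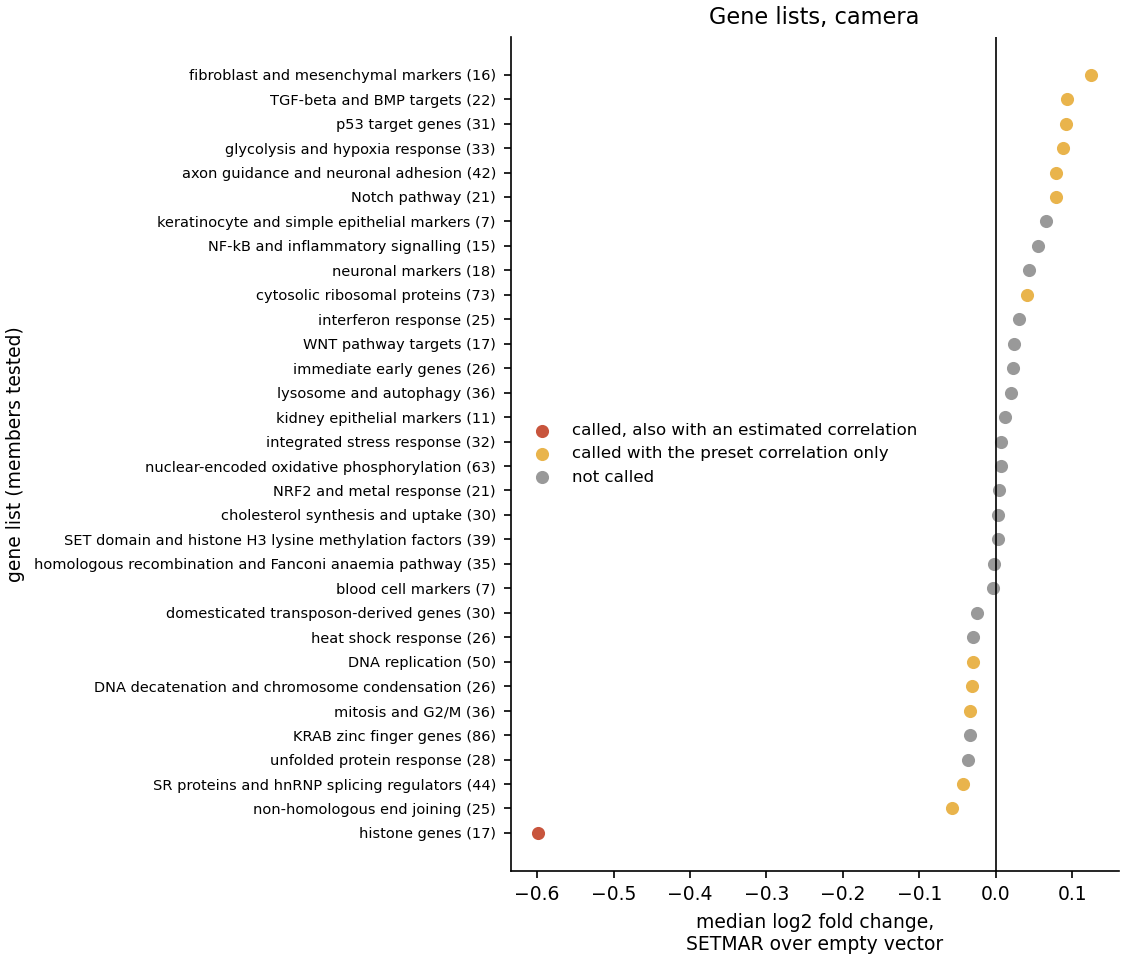
Median log2 fold change of SETMAR over empty vector for the 32 gene lists tested by camera, with the number of members tested in parentheses and colour showing the call. The histone list at -0.60 stands apart, while every other list lies between -0.06 and 0.12.

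The remaining lists were not called by camera in the main setting, while fry called the domesticated transposon-derived list lower (adjusted p = 0.0492) and the keratinocyte and simple epithelial list higher (adjusted p = 0.0214). With offsets, camera called 8 lists, of which 6 were among the 13, and without empty vector 1 it called 14, with all 13 among them. Some of the remaining lists were thus called by camera in other settings. Chromatin and transposon lists related to the domains of SETMAR had medians near 0: 0.0022 for 39 SET domain and histone H3 lysine methylation genes (EZH1 at 0.22, SE 0.06, adjusted p = 0.169), -0.03 for 30 domesticated transposon-derived genes (THAP1 at -0.21, SE 0.07) and -0.03 for 86 KRAB zinc finger genes. No member of these lists passed over all genes or adjusted over the list alone. Medians were 0.02 for 26 immediate early genes (FOS at -0.30, SE 0.08, adjusted p = 0.136 over all genes, the 1 member that fell adjusted over the list alone, at 0.0326), 0.05 for 15 NF-kB genes, -0.0031 for 35 homologous recombination genes, 0.01 for 63 oxidative phosphorylation genes, 0.0025 for 30 cholesterol genes, 0.02 for 36 lysosome genes and 0.02 for 17 WNT targets. Among markers of other cell types, 18 neuronal, 11 kidney epithelial, 7 blood and 7 keratinocyte genes had medians of 0.04, 0.01, -0.0038 and 0.07. The keratinocyte and simple epithelial marker MUC1, at 0.66 (SE 0.17, edgeR adjusted p = 0.131 over all genes), was the 1 member of these lists that rose adjusted over the list alone. The median, the mean and the direction of camera differed in sign for 5 lists. The heat shock list had a median of -0.03, a mean of 0.13 and a lower direction. Immediate early genes had a positive median with a mean of -0.0022 and a lower direction, and SET domain genes a positive median with a mean of -0.00092 and a lower direction. Blood cell markers had a negative median, a mean of 0.0047 and a higher direction, and cholesterol genes a positive median, a mean of 0.0045 and a lower direction.

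Beside depth, the share of reads mapped uniquely differed between the groups. Reads not uniquely mapped made up 11.1 ± 0.739% of reads with empty vector and 7.99 ± 0.507% with SETMAR, with non-overlapping groups (SD, n = 4 per group; exact permutation test, two-sided p = 0.0286, adjusted p = 0.0571). With SETMAR and GH1 reads left out, uniquely mapped reads made up 88.9 ± 0.740% and 91.7 ± 0.543%, again without overlap (exact permutation p = 0.0286, adjusted p = 0.0571). The RNA integrity number averaged 9.73 ± 0.126 and 9.68 ± 0.0957, and mitochondrial reads made up 0.584 ± 0.148% and 0.766 ± 0.161% (exact permutation p = 0.657 and 0.171). Fold change ran with expression level and GC content across genes (Spearman's rho -0.25 and 0.26, genes not being independent replicates), and offsets that removed both trends gave 222 genes past the threshold, an alternative chosen after seeing the data. All 40 genes were among the 222.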

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

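The tests of S phase, of a general heat shock response and of plasmid sequence in GH1 were chosen after the results were seen. Among 314 groups of 4 values checked (145 named genes and 12 library measures in each group), 14 held a library far from the other 3, where chance gives about 1 in 20, or 15.7. Of these, 6 were in empty vector 4, the shallowest library. XRCC5 stood at 824 CPM in empty vector 4 against 738 to 742 in the others, and ORC3 at 60.8 against 56.9 to 57.5. ZNF561 stood at 41.6 CPM there against 34.7 to 35.5, TRA2B at 314 against 303 to 304, NEFL at 201 against 217 to 218 and CD8A at 1.46 against 1.26 to 1.28. HMOX1 stood at 131 CPM in empty vector 1 against 142.4 to 143.1 in the other empty vector libraries. NFKB1 stood at 34.1 CPM in empty vector 3 against 35.7 to 35.9. In SETMAR 1, SLC12A4 stood at 36.8 CPM against 32.8 to 33.3 and NKD2 at 22.0 against 20.6 to 20.7. In SETMAR 2, LOC101927765 stood at 2.88 CPM against 3.63 to 3.73 and DOT1L at 99.2 against 109 to 110. In SETMAR 3, TRA2B stood at 287 CPM against 276 to 277 and NPC2 at 53.5 against 60.2 to 60.9.

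The decrease of the histone genes was weighed against technical explanations. Offsets for GC content, length and level left the median of the 17 list members at -0.65, and the summed CPM of the 27 HIST genes fell with a log2 ratio of -0.50, which argues against a general trend and against reads re-split between near-identical copies. Most replication-dependent histone mRNAs lack poly(A) tails, so a different carry-over of such RNA may contribute. The 41 other RNAs listed as lacking poly(A) tails had a median of -0.12, between the bounds set beforehand, so this stays open. Among them MALAT1 and NEAT1 stood at 0.34 and 0.34, but both were picked after their values were seen and do not weigh against carry-over. H1F0, a histone gene with a polyadenylated mRNA, also fell (-0.17, SE 0.03, edgeR adjusted p = 0.0256, not tested with libraries left out). Fewer cells in S phase could lower histone mRNAs too; the DNA replication list had a median of -0.030 over 50 members, which does not exclude it, since how strongly those genes follow S phase is not known from these data. An effect of SETMAR itself on histone transcripts also stays open, untested.

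The rise of HSPA6 was weighed in the same way. No stretch of its transcript matched the SETMAR coding sequence at 90% identity or more (0 bases), which argues against reads of the transfected gene. The larger of the log2 fold changes of HSPA1A and HSPA1B was 0.032, which argues against reads shared with these genes. Reads shared with other relatives of HSPA6 were not tested, so its assignment stays uncertain. Of the other 25 heat shock list members 0 rose over all genes, HSPA1A stood at -0.06 (SE 0.13) from a low level of 3.06 CPM, and adjusted over the list alone HSPB1 and SERPINH1 rose while HSPA8, HSPE1 and DNAJA1 fell; a general heat shock response was not seen, and one too small for the test is not excluded. An effect of SETMAR on HSPA6 is a candidate explanation that these data do not test further. With empty vector as the only control, such an effect cannot be told apart from one of strongly expressing any plasmid gene.

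GH1 stood at 3062 CPM with empty vector. A candidate explanation is reads from growth hormone sequence of the plasmid, whose backbone may carry a growth hormone polyadenylation signal. For reads from growth hormone sequence of the plasmid, the test counted pituitary genes listed, and 1 of the 6 named was listed (POMC). Such a count does not show where GH1 reads come from, so the test did not decide, and the plasmid sequence was not used here. An effect of SETMAR on GH1 itself stays open and untested.

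The 40 genes past the threshold were set against other groupings of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave 40 or more genes, the real one, and the highest of the others gave 15. The other splits each mix the groups, so group differences widen their spread, and they do not show what chance alone gives. Depth and the share of uniquely mapped reads also separated along the real split. The splits therefore do not show what the 40 genes are due to.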

How the results depend on the processing

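The thinning and the offsets were chosen after seeing the data. Whether the replicate numbers pair the samples is not settled, and the main test did not use them. Same-numbered deviations correlated at 0.12, 0.27, 0.03 and -0.06, and 2 of the 4 empty vector libraries correlated best with their own number. With the number as a block, 86 genes passed, 41 higher and 45 lower, all 40 among them, and camera called 13 lists. Genes past the threshold, 40 in all, were 89 with DESeq2 (31 higher, 58 lower), 151 with the likelihood ratio test (68 higher, 83 lower), 222 with offsets (94 higher, 128 lower) and 9 against a fold of 1.2. The causes were not tested. DESeq2, the likelihood ratio test and the offsets each kept all 40. With each library left out, the count ran from 19 to 77, genes higher from 3 to 25, genes lower from 16 to 61, and genes changed at least 2-fold from 7 to 9. Lists called by camera were 1 with an estimated correlation, 6 with fry (4 of them among the 13) and 8 with offsets (6 among the 13), and 9 to 14 with a library left out. The SETMAR log2 fold change ran from 8.72 to 8.99. With a library left out the decatenation list ran from -0.053 to 0.0051, the direction turned without empty vector 4, and with offsets camera's direction for the mitosis list turned at a median of -0.00042. ITGAM ran from -0.28 to 0.037 and DSP from -0.091 to 0.014, both turned without SETMAR 2. Of 24 named genes called beside SETMAR, 13 stayed past the threshold in every setting other than glmTreat against a fold of 1.2. The 9 genes past glmTreat were SETMAR, GH1, HSPA6, STAM-AS1, HIST2H2BE, HIST1H3B, HIST1H2AC, HIST1H4D and HIST1H3H. HMOX1, HIST1H1C, LOC100272217, C18orf65 and LOC101927765 passed in the other settings but not there. Of 120 named genes not called, 30 passed under at least 1 other setting. The median log2 fold change of all genes was at most 0.012 under the scalings. At these depths, simulated 1.2-fold changes were recovered in 62.1% of cases, so small changes can be missed.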

Other observations

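The test of neighbouring genes was chosen after the names of the genes were seen; the search for transposon-derived sequence was fixed before its result. Of the 17 genes that fell once the HIST genes and the histone gene H1F0 were left out, 10 (58.8%) had a gene on the opposite strand whose start lay within 1000 bases of their own, against 2433 of 13686 other genes (17.8%; Fisher's exact test, two-sided p = 0.00018). The pairs included POLR3C, an RNA polymerase III subunit gene, at -0.28 (SE 0.05) beside RNF115 at -0.05 (SE 0.05), TAF9, a TFIID and SAGA subunit gene, at -0.25 (SE 0.04) beside RAD17 at -0.03 (SE 0.06), and DPH3 at -0.22 (SE 0.05) beside OXNAD1 at -0.04 (SE 0.06). STAM-AS1 at -0.99 (SE 0.13) lay beside STAM at -0.02 (SE 0.06), C10orf111 at -1.22 (SE 0.24) beside RPP38 at -0.11 (SE 0.06), and C16orf93 at -0.43 (SE 0.08) beside RNF40 at -0.02 (SE 0.04). The partners of these 10 genes did not pass the threshold, adjusted p running from 0.480 to 0.998, and the differences within pairs were not tested. The test was run on the genes whose names prompted it, and the other genes were not matched on type or level, so its p-value is not independent evidence of a link between neighbouring genes and SETMAR.

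Genes carrying sequence like the Hsmar1-derived part of SETMAR were examined for a response to SETMAR binding or for misassigned reads. Whether SETMAR binds sequence like its own coding sequence is not known from these data. Of the genes tested, 7 (BCL7C, FGD5-AS1, GLCE, NSD1, PGM3, PSMA3-AS1 and TTC28-AS1) had a transcript matching the SETMAR coding sequence over 100 bases or more. Their median log2 fold change was -0.020, within the central 95% of 10000 random sets matched on level (-0.07 to 0.06), and 0 passed the threshold with edgeR. With 7 genes, only a shift of the whole set beyond those bounds could have been seen. The longest matches were 83.2 to 87.2% identical, and how many SETMAR reads would be assigned at such identity was not tested. The test therefore decides on neither binding nor misassigned reads. The search compared annotated transcripts with the SETMAR coding sequence, so sites outside transcripts or unlike the coding sequence were not examined. The search does not bear on where SETMAR binds in the genome.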
